A study of Zea mays with 10 samples.

How the data were processed

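Leaf RNA of field-grown maize was compared between plots sown with a weed, velvetleaf, and plots kept largely free of weeds by hand. Each of 8 plots, 4 weedy and 4 control, gave a pool of leaf from 4 plants, and 10 arrays each set a weedy pool against a control pool in the dyes Cy5 and Cy3, per the labels. The weedy pool was in Cy5 on 5 arrays and the control pool was in Cy5 on the other 5. A pool was used on 2 to 4 arrays, with control plot 4 on 4 arrays and weedy plots 1 and 3 on 3 arrays each. Weedy plot 4 was labelled in Cy5 on both of its arrays and never in Cy3.

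The deposited value table held 1 log ratio per array element and array, for 19200 elements, and was treated as log2. The deposited log2 values came without a statement of the log base, of the numerator channel or of the normalization; the scanner, background correction and filters are not given in the sources used here. Base 10 was set aside because the largest value, 7.64 in size, would exceed what a scanner can record, and base 2 and the natural base could not be told apart. If the values are natural logs, all sizes given as log2 are too small by one common factor, and tests are unaffected. Array medians were close to 0, at -0.04, -0.03, -0.01, -0.01 and 0.02 with weedy RNA in Cy5 and 0.0027, 0.06, 0.01, 0.03 and 0.03 with control RNA in Cy5. No signal or background value was used here, so precision was limited by the number of arrays and a filter on dim spots was not run. No element had been marked as dim in the table.

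An element was tested if it had a value on at least 4 arrays of each dye orientation, which left 16201 elements. No array had a value for 1817 elements, and 9486 elements had a value on all 10 arrays. Each array was centred on its median. Per element, the ratio was fitted by generalised least squares with a treatment term (+1 with weedy RNA in Cy5, -1 with control RNA in Cy5) and a dye intercept. The 8 plots were a random effect, with 1 ratio of plot variance to array variance for all elements, estimated by restricted likelihood on the complete elements. Variances were moderated with eBayes in limma 3.58.1 under R 4.3.3, and p-values were adjusted over all tested elements by the Benjamini-Hochberg method at a threshold of 0.05. All p-values named as adjusted p come from limma or its cameraPR set test.

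In the text, a positive turned ratio means weedy above control if the deposited values run Cy5 over Cy3. If they run Cy3 over Cy5, every sign is the opposite. If every array had been turned to weedy over control before deposit, the treatment and the dye terms exchange places, and this reading was run as an alternative. The readings were compared by restricted likelihood with 1000 bootstraps over elements, and the plot ratio had 100 bootstraps.

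Elements were named through the platform annotation in a table supplied with the values. It gave 1 gene for 1800 elements and several genes for 23, and no name for 17377, which are unnamed here and may still carry genes. The 1800 elements held 583 genes, of which 562 matched by gene identifier a RefSeq table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. Names such as PIP2-6 are synonyms in that table. The symbol MNB1b stood on 230 elements against at most 28 for another symbol and was left out of gene results. Elements of a gene were averaged for gene and list tests, which left 540 genes.

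Gene lists were fixed before the data were examined as 26 word patterns. Because the annotation gave symbols without descriptions, only 3 of them reached the minimum of 5 genes. After the annotation and the top of the ranking had been seen, 21 lists were assembled by symbol, of which 16 could be tested; the themes of translation factors, glycolysis and tubulins had not been fixed beforehand. List tests used cameraPR with a preset correlation of 0.01 and again with the correlation estimated from the data.

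The rule for named elements, also fixed before the data were examined, took up to 12 named elements per direction past the threshold, and otherwise the 6 of smallest p per direction, given as not passing. It also took up to 4 genes of smallest p per fixed list and at most 2 unnamed elements per direction. For lists assembled by symbol, the gene of smallest p was taken, a choice made later. Alternatives covered centring, scaling, independent arrays, 1 value per plot, no dye intercept, the plot number as a block, stricter and weaker filters on missing values, robust moderation, array weights, the other reading, and each array and each plot left out. Removal of block medians, removal of row and column medians, and turning the sign of the 2 arrays with control plot 4 in Cy5 were added after seeing the data.

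The fit was tested on simulated data with the design, missing values and spreads of the weedy against control comparison, 16201 elements and 200 changed ones. It called 52 of 67 elements simulated at a log2 ratio of 0.5, 67 of 67 at 1 and 66 of 66 at 2, none with the wrong sign. Of its calls, 7.96% were unchanged elements. The simulated noise was independent between elements, while neighbouring elements correlated at 0.242 in the data. Of the unchanged elements, 4.96% had an unadjusted p under 0.05, against 12.1% of all elements tested in the data. The rates from simulation may therefore not hold for the measured arrays. With 1 value per plot, the fit ran on 16079 elements and called 1 of 67 at 0.5, 50 of 65 at 1 and 65 of 65 at 2.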

Results

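The series asked how growing among velvetleaf, a broadleaf weed, altered transcript levels in maize leaves. It held 10 arrays of 2 colours, each with a pool of leaf from a weedy plot against a pool from a control plot, and 8 pools in all. The number of elements with a value ranged from 9965 on array 5 with control RNA in Cy5 to 17383 on array 4 with weedy RNA in Cy5. The SD of the deposited ratios within an array ranged from 0.31 to 0.59. Arrays are named by the treatment in Cy5 and their number within that orientation.

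The direction of the deposited ratios was not stated, and every sign below depends on reading them as Cy5 over Cy3. Sizes, counts and calls depend on it too, because the treatment and dye terms exchange places if the arrays had been turned before deposit. On the Cy5 over Cy3 reading, the log likelihood was higher by 34.6 (95% bootstrap interval 18.0 to 49.6) than if all arrays had been turned to weedy over control before deposit. After block medians were removed the difference was -33.5 (95% bootstrap interval -48.4 to -18.5), in favour of the other reading, so the direction was not settled. Both intervals come from resampling elements, which share the same arrays and plots, so they leave out the spread between arrays and plots. Over elements, which are not independent, arrays of the same dye orientation had a median correlation of 0.108 in 20 pairs, with a lowest value of -0.06. Arrays of opposite orientation had a median of -0.05 in 25 pairs, with a range from -0.298 to 0.233 and 10 pairs above 0.

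On the Cy5 over Cy3 reading, weedy and control leaves differed past the threshold at 2 of 16201 elements, both without a gene name here. Element_16564 had a turned log2 ratio of -1.96 (SE 0.17, adjusted p = 0.000945), negative on 8 of the 8 arrays with a value. The 2 arrays without a value were those that hold control plot 3, so that plot does not enter this ratio. Element_15339 had a turned log2 ratio of 1.63 (SE 0.22, adjusted p = 0.0247), positive on 10 of 10 arrays. They were the 2 elements with a fitted size above 1, and the median size over all elements was 0.104. At an unadjusted p under 0.05 there were 1964 elements, 12.1% of those tested, of which 1162 were positive and 802 negative. The dye term of the same fit, which takes the place of the treatment on the other reading, had 687 positive and 851 negative. The lean to positive ratios thus depends on the reading.

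**Figure D1:**
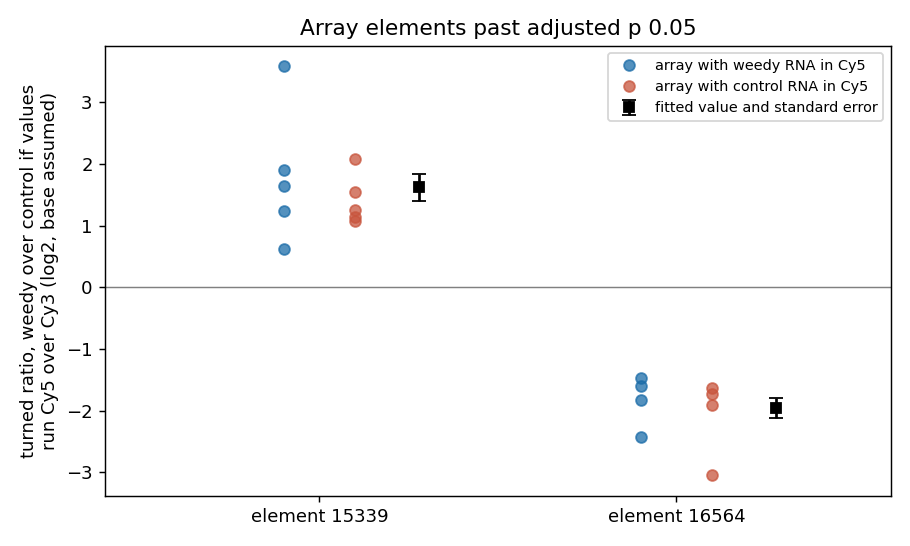
Turned ratio (log2, base assumed; vertical axis) of the elements past an adjusted p of 0.05 on each array (points, by the treatment in Cy5), with the fitted value and its standard error (squares). All 10 arrays lie above 0 for element 15339, and all 8 arrays with a value lie below 0 for element 16564.

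With 1 value per plot, or with the values read as already turned, 0 elements passed, and 1.60% and 9.09% of elements had an unadjusted p under 0.05. On simulated data, 1 value per plot gave such a p to 0.497% of unchanged elements, against 4.96% with the main fit. The 1.60% therefore does not show that the excess was absent. Element_16564 could not be tested with 1 value per plot, as it had no value for control plot 3. Without control plot 4 or without weedy plot 3 the count was 0 as well, at ratios of -2.02 and -1.77 for element_16564 and 1.94 and 1.86 for element_15339, and without array 1 with control RNA in Cy5 it was 4. With the plot number as a replicate block element_16564 did not pass (-2.00, adjusted p = 0.0649). On the other reading the ratios were 0.12 for element_16564 and 0.19 for element_15339, and with the 2 arrays that hold control plot 4 in Cy5 turned, whose direction is in doubt, they were -1.16 and 1.22 and 0 elements passed. The count was 1 without any of arrays 1, 2 and 5 with weedy RNA in Cy5, arrays 2 to 5 with control RNA in Cy5, control plots 1 and 2, or weedy plots 1 and 2. In these the call lost was that of element_15339, which kept its sign in 32 of 32 alternatives.

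No named gene differed past the threshold. Of 540 genes tested with limma, 0 had an adjusted p under 0.05 and 64 had an unadjusted p under 0.05, 39 of them positive. In other settings Lsi6 (LOC542497), a silicon channel of the aquaporin family, passed with array weights (0.68, adjusted p = 0.044), with the plot number as a replicate block (0.64, adjusted p = 0.0276), without array 3 with control RNA in Cy5 (0.70, adjusted p = 0.0491) and without weedy plot 2 (0.77, adjusted p = 0.0153). zmm24 (LOC542038) passed with array weights (-0.43, adjusted p = 0.044), and toc34B (LOC542012), named here after its values were seen, passed without array 3 with control RNA in Cy5 (-0.43, adjusted p = 0.0491). The positive named elements of smallest p included element_6396, for Lsi6, at a log2 ratio of 0.61 (SE 0.13, adjusted p = 0.211). Among them were also elements of the sucrose synthase sus1 (LOC542247, element_19132) at 0.49, the glyceraldehyde-3-phosphate dehydrogenase GAPC1 (LOC542367, element_13829) at 0.44, and the enolase eno1 (LOC732811, element_10452) at 0.45. The elongation factor element elfa2 (LOC100037748, element_6037) was at 0.63 and the element of TLK2 (LOC542152, element_19155) at 0.42. None of these passed, and other elements of the same genes did not always share the sign: 18 of 24 did for elfa2, 3 of 6 for sus1, whose gene value was 0.0017, 0 of 1 for TLK2, 4 of 5 for GAPC1 and 4 of 5 for eno1.

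The negative named elements of smallest p did not pass either. They were the glutathione transferase gst10 (LOC541828, element_8057) at -0.54 (SE 0.11, adjusted p = 0.211), zmm24 (LOC542038, element_11646), a MADS box gene, at -0.40, and paa (LOC542021, element_8447) at -0.38. The remaining ones were pk8-b (LOC732828, element_8548) at -0.35, LOC542727 (element_8071) at -0.34 and pk4 (LOC541785, element_8513) at -0.31. The elements of zmm24, LOC542727 and pk4 were negative on 10 of 10 arrays. The other elements of the same gene shared the sign in 1 of 2 for gst10, 3 of 4 for paa, 4 of 4 for pk8-b and 1 of 3 for LOC542727.

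Aquaporins, channels for water and small solutes in membranes, had positive turned ratios in 10 of the 10 genes measured, with a mean log2 ratio of 0.19 (SD over genes 0.153, adjusted p = 0.00617, cameraPR with the preset correlation). The list did not pass with an estimated correlation, at an adjusted p = 0.087. Over all genes 0 members passed, and adjusted over the list alone 1 did. That gene was PIP2-6 (LOC541891), a plasma membrane channel, at 0.31 (SE 0.07), positive on 10 of 10 arrays, with a limma adjusted p of 0.0143 over the list alone. PIP2-4 (LOC541890) stood at 0.42 (SE 0.19), PIP1-5 (LOC542014) at 0.15 (SE 0.08) and PIP1-3 (LOC541886) at 0.13 (SE 0.07), none of which passed. The list also missed the threshold after row and column medians were removed (mean 0.12, adjusted p = 0.0973) and with array weights (mean 0.12, adjusted p = 0.129). On the other reading its mean was -0.13, and with the 2 arrays that hold control plot 4 in Cy5 turned, it was 0.08 (adjusted p = 0.621). Without array 2 with control RNA in Cy5, or without control plot 3, its mean was 0.14 and the adjusted p was 0.0693 and 0.0822.

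Light harvesting and photosystem genes did not pass as a list, with a mean of 0.14 over 7 genes (adjusted p = 0.125), 5 of them positive. The list passed on the other reading, with a mean of -0.19 (adjusted p = 0.0378). It also passed without array 5 with weedy RNA in Cy5 (0.19, adjusted p = 0.0286), without control plot 4 (0.16, adjusted p = 0.0414), without weedy plot 1 (0.20, adjusted p = 0.0231) and without weedy plot 4 (0.22, adjusted p = 0.00852). The mean was smaller without weedy plot 3 (0.08, adjusted p = 0.448) and without control plot 1 (0.09, adjusted p = 0.561), and was 0.0074 (adjusted p = 0.972) with the 2 arrays that hold control plot 4 in Cy5 turned. The photosystem I subunit psaH (LOC541685) was at 0.40 (SE 0.14), the antenna protein gene lhcb5 (LOC542716) at 0.15, psbs1 (LOC542126), which acts in the dissipation of excess light, at 0.22, and psaN (LOC542605) at 0.21. Adjusted over the list alone, 0 genes passed. Ribosomal protein genes lay near 0, with a mean of 0.01 over 13 genes (adjusted p = 0.642), and adjusted over the list alone 0 passed. Their genes of smallest p were RPS21 (LOC542449) at 0.21 (SE 0.21), rpl17 (LOC541667) at -0.05, RPL27A at -0.05 and RPL10 (LOC542298) at 0.04.

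**Figure D2:**
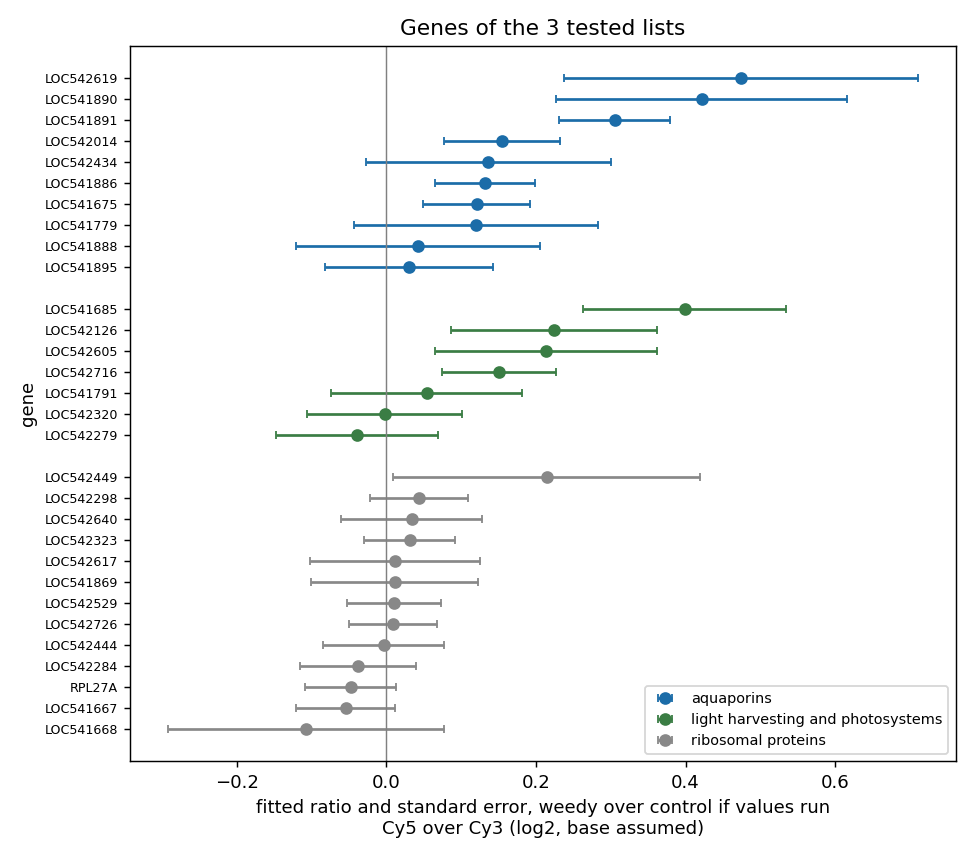
Fitted log2 ratio and standard error (horizontal axis, weedy over control if the values run Cy5 over Cy3, base assumed) of each gene (vertical axis) in the 3 fixed lists that could be tested. All 10 aquaporins lie above 0, with a mean of 0.19, while the 13 ribosomal protein genes scatter around a mean of 0.01.

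Among the 16 lists assembled by symbol after the annotation and the top of the ranking had been seen, the aquaporin list held the same 10 genes and Lsi6, a top-ranked one, so that its result is not independent evidence (mean 0.23, adjusted p = 0.00144, and adjusted p = 0.107 with an estimated correlation). None of the other 15 passed. The median ratio over all 540 genes tested was 0.02, above 0, so a list with most genes positive does not by itself differ from the other genes. Light harvesting genes were positive in 7 of 9 and ribosomal protein genes in 10 of 17. Glycolysis and fermentation enzymes had a mean of 0.10, with 7 of 10 genes positive (adjusted p = 0.452). Carbon fixation enzymes had a mean of 0.09, with 6 of 7 positive and the malate dehydrogenase mdh6 (LOC542374) at 0.34 (SE 0.15). Genes of oxidative stress and glutathione were positive in 18 of 27, with the peroxidase PRX2 (LOC542571) at 0.22 (SE 0.06). Their mean, 0.016, lay below the mean of the genes outside the list, 0.027. Sucrose and starch genes were negative in 9 of 13, with the starch synthase zSSIIa (LOC542481) at -0.12. For chaperones 10 of 14 were positive, with hsp70-4 at 0.15 (SE 0.06), and for histones and cell division 9 of 16, with cdc2 (LOC542270) at -0.18 (SE 0.08). Hormone genes of the gibberellin, brassinosteroid and cytokinin list were positive in 2 of 6, with an1, an enzyme of gibberellin synthesis, at 0.37 (SE 0.13). In the abscisic acid list 4 of 5 were positive, and COR413-TM1 (LOC542100), at -0.23 (SE 0.07), was negative on 10 of 10 arrays and the 1 gene to pass adjusted over the list alone. Defence genes were positive in 2 of 5, with the chitinase chn1 (LOC542525) at 0.21, and cell wall genes in 5 of 13, with the expansin expB8 (LOC542496) at 0.12. Translation factors were positive in 9 of 12, with EF1A (LOC542581) at 0.13, and tubulins in 5 of 11, with tua3 (LOC542395) at 0.06. Genes listed under kernel and pollen, organs that were not sampled, were positive in 5 of 8, with ohp1 (LOC542704) at 0.37 (SE 0.10). That gene was the 1 to pass adjusted over the list alone. Whether the listed genes are confined to those organs was not checked. Neither COR413-TM1 nor ohp1 passed over all genes.

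With the values read as Cy5 over Cy3, the ratio of plot variance to array variance was 0.0347 (95% bootstrap interval over elements 0.0263 to 0.0418) and was 0 after block medians were removed. On the other reading it was 0 before and 0.0328 after that removal. On the first reading it ranged from 0 to 0.171 with 1 array left out, the highest without array 4 with control RNA in Cy5, and was 0.262 without weedy plot 3. For the dye term 0 elements passed in limma, and 1538, or 9.49%, had an unadjusted p under 0.05, against 12.1% for the treatment term. Neighbouring elements of the table shared part of their values, with a mean correlation of 0.242 within an array.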

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

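The test of position was chosen after the result was seen. Array 3 with weedy RNA in Cy5 lacked a value for 5453 elements, against 1817 to 1972 on the other arrays of its orientation. Array 5 with control RNA in Cy5 lacked 9235, against 1826 to 2967. Of 34 checks, each of 1 measure within 1 dye orientation, these 2, both of the same measure, found an array far from the others. Chance gives about 1 in 20 for a single check. Most of the checks were of the named elements, which were mostly chosen for small p and so for agreement between arrays. The share of checks flagged therefore does not say whether the missing values arose by chance.

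The excess of small p-values was weighed against position on the array. Elements next to each other in the table correlated at 0.242, and the correlation was -0.004 once row and column medians were removed, yet 13.5% of elements then had an unadjusted p under 0.05 against 12.1% before. The plot ratio was 0.0347 before and 0 after. With the 10 arrays taken as independent, a ratio of 0 as well, the share before removal was 14%. At equal ratio, the share thus went from 14% to 13.5% when row and column medians were removed, which argues against position as its whole source. With block medians removed, also at a ratio of 0, it was 15.8%. Such removal can lower noise as well, so the change in share does not measure how much position contributed. The share itself depended on the plots and arrays used, from 4.75% without weedy plot 3, which left 7 arrays, to 16.8% without weedy plot 2, which left 8. With 1 array left out it ranged from 7.30% without array 4 to 15.0% without array 3 with control RNA in Cy5. Splits of the plots other than the real one reached 12.2% and 12.4%, with 6 and 8 informative arrays. Each of these 2 exchanges only 1 plot per side, so it keeps part of the weedy against control contrast. Splits with 2 plots of each treatment on each side reached at most 8.2%, there with 3 informative arrays. The splits therefore do not decide whether the share is particular to the real grouping. For the dye term of the same fit the share was 9.49%, so an excess of small p-values was not particular to the treatment term. A difference between plots other than the weeds stays open, and an effect of the weeds was not tested apart from it.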

How the results depend on the processing

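Removal of block or row and column medians and turning the 2 arrays with control plot 4 in Cy5 were chosen after seeing the data, and the other settings before. The count of 2 elements became 1 with scaling between arrays, 0 with 1 value per plot, 0 on the other reading, 0 with the 2 arrays turned and 6 with array weights. It lay between 0 and 4 with an array or a plot left out. Element_16564 stayed past the threshold in 25 of 30 alternatives and element_15339 in 14 of 32. Leaving out control plot 3, or either array that holds it, removed no value of element_16564, so these alternatives do not test its ratio. With 1 value per plot element_15339 stood at 1.84 and element_16564 gave no value, for lack of control plot 3. On the other reading element_15339 stood at 0.19, and with the 2 arrays turned they stood at 1.22 and -1.16. The cause was not tested.

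The 1 fixed list past the threshold became 0 with elements on all arrays only, array weights, row and column medians removed, each element as a member, an estimated correlation and the 2 arrays turned, and lay between 0 and 2 with an array or a plot left out (2 without array 5 with weedy RNA in Cy5, control plot 4, or weedy plot 1 or 4, light harvesting being the second list). On the other reading the 1 list was light harvesting, not aquaporins. The aquaporin mean was 0.13 (adjusted p = 0.0714), 0.12 (0.129), 0.12 (0.0973), 0.14 (0.0946), 0.19 (0.087) and 0.0819 (0.621) under these, and -0.13 (0.0993) on the other reading. With an array or a plot left out it lay between 0.14 and 0.27. It was past the threshold in 25 of 34 alternatives, over which the adjusted p ranged from 0.000111 to 0.621. The cause was not tested.

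The likelihood difference between readings was -33.5 after block medians and -43 after row and column medians were removed, and the plot ratio was 0 in both on the Cy5 over Cy3 reading and 0.0328 and 0.038 on the other. The cause was not tested. The dye count was 0 in every setting it was run in.

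On the other reading the sign turned for element_10452 (-0.10), element_13829 (-0.14), element_16564 (0.12), element_6037 (-0.54), element_6396 (-0.27), element_8071 (0.029) and element_8513 (0.0028). It also turned for the genes hsp70-4 (-0.18), LOC541667 (0.0103), LOC541685 (-0.34), LOC541886 (-0.13), LOC541890 (-0.13), LOC542126 (-0.27), LOC542298 (-0.0158), LOC542367 (-0.34), LOC542374 (-0.49), LOC542395 (-0.13), LOC542449 (-0.092), LOC542481 (8.2e-05), LOC542525 (-0.11), LOC542581 (-0.14), LOC542605 (-0.45) and LOC542704 (-0.11). With the 2 arrays turned it turned for hsp70-4 (-0.0186), LOC541667 (0.0322), LOC542126 (-0.145), LOC542367 (-0.0267), LOC542374 (-0.0066), LOC542395 (-0.0234) and LOC542605 (-0.0735). None passed in either.

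Control and weedy plots share numbers. Correlations over elements between same-numbered plots were -0.51, 0.12, -0.61 and 0.21 for numbers 1, 2, 3 and 4. The highest correlation with a plot of another number was 0.56, 0.49, 0.71 and 0.28. Only the plots numbered 4 were set against each other on an array. Which pools shared an array may shape these correlations, so they cannot decide whether same-numbered plots deviate together. With the replicate block of plot number, 2 elements passed, 1 of them, element_15339, shared with the fit without it, while element_16564 did not pass (-2.00, adjusted p = 0.0649). Without signal values, no limit from dim spots could be set.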

Other observations

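The tests of position and of array direction were chosen after the results were seen, and those of splits and of member correlation before. Lists assembled by symbol with under 5 genes were not tested. Negative turned ratios were found in 3 of 4 nitrogen assimilation genes, 3 of 4 phenylpropanoid genes, 3 of 3 jasmonate genes, 2 of 3 auxin genes and 2 of 3 genes of metal transport, none past the threshold.

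The symbol MNB1b stood on 230 elements, and pairs of them had a median correlation of 0.15 over arrays, as did pairs of elements of 1 other gene (0.15), against -0.0008 for random pairs. Treatment ratios of element pairs of 1 gene correlated at 0.17 over 3748 pairs, and those of neighbouring elements at 0.22.

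Of the 35 splits of the 8 plots into 4 and 4, 1 gave as many passing elements as the real 2, the real one itself, and the highest other count was 1. The other splits had 3 to 8 informative arrays against 10, which lowers their counts by design, so chance is not excluded. For the fixed lists, 10 of 35 splits gave at least the real count of 1, and the highest other count was 2, so chance is not excluded for the count of lists. The counts take any of the 3 fixed lists. The aquaporin list was not counted by itself, so chance stays open for it.

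The aquaporin mean went from 0.19 (SE over genes 0.05) to 0.124 (SE 0.04) when row and column medians were removed, with 9 genes positive. The call ended as the distance of the list from other genes in moderated t went from 1.42 to 1.06 while the SD of t over other genes went from 1.38 to 1.5. Position may account for part of it and the test leaves the rest open. The 6 members with all values correlated at 0.133 with each other, above the median of 1000 random lists (-0.0008) and below their 95th percentile (0.216), so shared sequence or regulation stays open. An effect of the weeds stays open too, as its direction is not settled.

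Arrays 3 and 5 with control RNA in Cy5, which hold control plot 4, correlated at a mean of 0.172 with the arrays that hold it in Cy3 (4 pairs), where values that all run Cy5 over Cy3 would give negative values from a shared plot. With the 3 weedy Cy5 arrays that lack it, the mean was -0.03 (6 pairs). Some of the 6 pairs share a weedy plot in opposite dyes, which can lower their mean. Arrays 1 with weedy and 3 with control RNA in Cy5 share weedy plot 2. Arrays 2 with weedy and 5 with control RNA in Cy5 share weedy plot 3. The lowest value of the 4 pairs, 0.083, still lay above the highest of the 6, 0.0744. The difference of 0.203 argues against a dye effect common to all arrays, though the pairs are not independent. If all arrays had been turned to weedy over control before deposit, a shared plot would give positive values too, so the 4 pairs alone do not single out these 2 arrays. A hypothesis is that these arrays may run in the opposite direction to the others: turning them ranked 1 of 45 pairs by likelihood, with a gain of 357. The highest gain of another pair was -1310, and the 2 readings of all arrays differed by 34.6. After turning, 0 elements passed, and the aquaporin mean was 0.08 (adjusted p = 0.621). The hypothesis was found and tested on the same values and stays open.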
